A study of Mus musculus with 10 samples.

How the data were processed

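The series holds 10 sequencing libraries from mouse (Mus musculus) tracheal epithelial organoids, which are multicellular structures grown in a gel from airway basal cells, the stem cells of the tracheal lining. Basal cells came from control mice (labelled Ctrl) and from mice labelled M3-CKO, which the series title gives as a Mettl3 knockout. Mettl3 is the catalytic subunit of the methyltransferase complex that writes N6-methyladenosine (m6A) on messenger RNA. Organoids were harvested on day 14. RNA-seq covered 6 libraries, 3 per group. The other 4 libraries came from m6A immunoprecipitation and its input, 1 of each per group, and were not analysed here, because the table used has no columns for them.

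Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was purified and fragmented, and libraries were read as pairs of 150 bases on a HiSeq instrument. The deposited counts are whole numbers of reads or read pairs per gene, not normalized. Per the submitters' processing notes, Trim Galore, HISAT2 and featureCounts were used with genome build mm39. Their versions, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical gene copies, overlapping genes and antisense genes can therefore have been shared, dropped or counted for a neighbour, and values of such genes are uncertain. The table names genes by symbol and gives no coordinates. No genome sequence was used, so no positions are printed.

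The table lists 22457 genes, and 0 of them had a count of 0 in all 6 libraries. A gene with no row has no value here, and whether it was counted at 0 or left out of the counting is not known. None of the 13 mitochondrially encoded genes looked up has a row. Total counts ran from 8906375 to 10485922 per library, so a level of 10 CPM (counts scaled to library size) rests on 89.1 to 104.9 counts. The floor of 3 counts used for Sp5 covers counting error only.

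Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr kept 13528 genes, libraries were scaled by TMM (factors 0.956 to 1.05), and the quasi-likelihood test (glmQLFit, glmQLFTest) compared M3-CKO with Ctrl, two-sided and with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this test unless another tool is named. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change was computed as its size over the square root of the F statistic. The labels do not say whether replicates are separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

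Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, over the 25 of 33 lists that had at least 4 tested members. The calls were repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. Of 477 list genes, 422 were matched to a row in the table. Loricrin and Rigi, of the squamous and interferon lists, were among those not matched under their listed names. Of the 422 matched genes, 2 were matched through an older symbol. This used a table of gene names on assembly GRCm38.p6 that served only for names and for the order of neighbouring genes.

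The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Mettl3, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap and whose mean is at least 5 CPM (leaving out predicted and clone names), up to 4 called members of each list with the lowest adjusted p, and 9 fixed genes (Krt5, Trp63, Krt13, Scgb1a1, Muc5ac, Foxj1, Mki67, Cdkn1a and Isg15). Of the genes the rule picks, 1 is not reported here. A gene outside the rule is marked as chosen after its values were seen. Alternatives were DESeq2 1.42.0 size factors, library size alone, the DESeq2 Wald test, limma-voom, no low-count filter, a stricter filter, a minimum fold of 1.5, leaving out the 20 most abundant genes, the replicate number as a block, and leaving out each library in turn. Summing M3-CKO replicates 1 and 2 was added after seeing the data.

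The edgeR steps were tested on simulated data with 13528 genes drawn from the means and library sizes of this comparison, of which 200 were changed. The test recovered 18.4% of the genes changed 2-fold, 82% of those changed 4-fold, 91.8% of those changed 8-fold and 100% of those changed 16-fold. It called 10 unchanged genes, 6.45% of its calls. In the simulation a change of 2-fold was therefore often missed. The simulation drew the noise of each gene on its own. It held no library that departs in many genes at once, as M3-CKO replicate 3 does, so the rates in the real data may differ.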

Results

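RNA-seq counts were compared between tracheal epithelial organoids grown from basal cells of Ctrl mice and of M3-CKO mice, 3 libraries each, harvested on day 14. The comparison asks which transcripts differ in level when organoids form from basal cells that carry the Mettl3 knockout. Totals were similar, from 8906375 counts in Ctrl replicate 3 to 10485922 in M3-CKO replicate 1, and between 17447 and 18444 genes had at least 1 count per library. The 3 Ctrl libraries lay together (Pearson r across genes of log2 CPM 0.967 to 0.977), and M3-CKO replicates 1 and 2 lay closer still (r 0.985). M3-CKO replicate 3 stood apart: its r was 0.919 and 0.908 with M3-CKO replicates 1 and 2, no higher than the 0.919 to 0.925 it reached with the Ctrl libraries. Genes are not independent replicates, so these r values describe the libraries only.

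**Figure D1:**
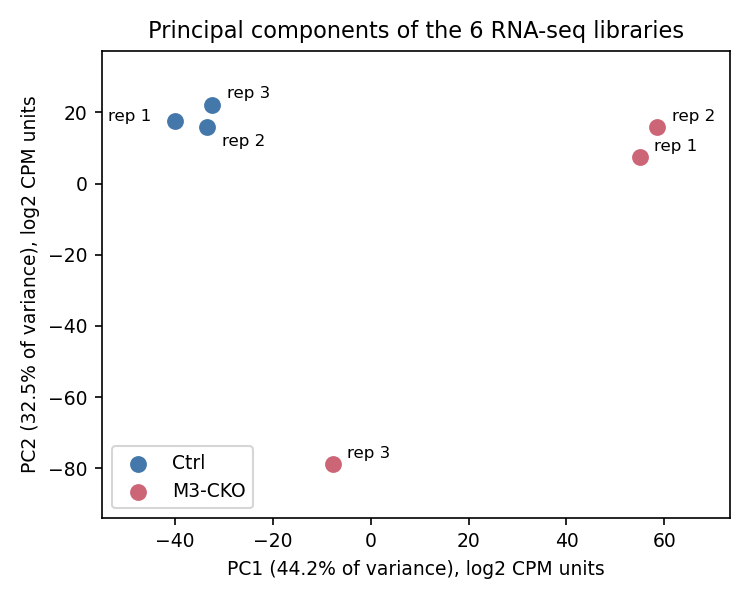
Principal components of log2 CPM over the tested genes, 1 point per library, blue for Ctrl and red for M3-CKO, with the replicate number beside each point. The first component (44.2% of variance) parts the Ctrl libraries from M3-CKO replicates 1 and 2, and the second (32.5%) parts M3-CKO replicate 3 from the other 5 libraries.

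Mettl3 was measured first, as the targeted gene. It stood at 14.96, 17.0 and 18.9 CPM in Ctrl replicates 1 to 3, and at 11.1, 10.3 and 9.87 CPM in M3-CKO replicates 1 to 3. The M3-CKO mean was 61.4% of the Ctrl mean, with every M3-CKO library below every Ctrl library. The log2 fold change of -0.70 (SE 0.21) did not pass the edgeR test over all genes (adjusted p = 0.12), and the two-sided exact permutation p of 0.1 is the smallest that 3 libraries against 3 allow. Without M3-CKO replicate 3 the adjusted p was 0.043. The deleted part of the gene is not given in the sources used here, and a whole-gene count can hold reads from outside it, so the count does not measure how much intact transcript was left. Mettl14, the partner subunit of Mettl3, had a log2 fold change of -0.12 (SE 0.17, adjusted p = 0.74; chosen after its values were seen).

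M3-CKO organoids held more RNA of C1s1, a complement protease, at 25.0 ± 7.13 CPM (SD, n = 3) against 0.647 ± 0.377 in Ctrl, and of Scgb1a1, the secretoglobin of club cells, at 159.8 ± 173.6 against 4.24 ± 1.38 CPM. Fosb, an immediate early transcription factor of the AP-1 family, fell from 200.7 ± 62.8 to 7.26 ± 4.40 CPM, and Dmbt1, a secreted scavenger receptor of mucosal epithelia, from 210.6 ± 56.6 to 10.9 ± 6.92 CPM. In all, 393 of 13528 tested genes were called by edgeR: 236 were higher and 157 lower in M3-CKO, 306 of them by over 2-fold. The groups did not overlap for any of the 393. Over all tested genes 27.1% had groups that did not overlap, where chance gives 10%.

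The count depends on single libraries. Without M3-CKO replicate 3 it was 3483 (1913 higher, 1570 lower), among them all 393 genes in the same direction. That fit shares all its libraries with the main one, so the return of the 393 is no independent check. Its M3-CKO group is replicates 1 and 2 alone, a closer pair (r 0.985) than any in Ctrl (at most 0.977). Whether they are separate animals or cultures is not known. Adjusted p values without replicate 3, wherever given, rest on this narrow spread and may be too low. Without M3-CKO replicate 1 or 2 the count was 14 or 18. Without Ctrl replicate 1, 2 or 3 edgeR called 0, 1 or 0 genes, with 2378, 2044 and 1963 at an unadjusted p under 0.05, against 2774 with all 6 libraries. All 32 called genes that the naming rule picked lost their call without any 1 of the 3 Ctrl libraries, and all 32 kept it without M3-CKO replicate 3.

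Among the other genes with the largest rises, Apobr, a lipoprotein receptor, had a log2 fold change of 5.01 (SE 0.86, adjusted p = 0.034). The transmembrane protein gene Tmem132b stood at 4.43 (SE 0.55, adjusted p = 0.019), Map1b, which encodes a microtubule-associated protein, at 4.26 (SE 0.68, adjusted p = 0.029), and Igfals, which encodes a carrier of insulin-like growth factors, at 4.16 (SE 0.63, adjusted p = 0.028). Pglyrp3, a peptidoglycan recognition protein, rose by 3.41 on the log2 scale, Plekhs1 by 3.34, Basp1 by 3.33 and Tmem95 by 3.31, with adjusted p from 0.0091 to 0.031. Among the other largest falls, after Fosb (log2 fold change -4.79, SE 0.54, adjusted p = 0.016), were those of Lgi2 (-4.35), Dmbt1 (-4.27) and Car12, a carbonic anhydrase (-4.04). Aldh1a3, an enzyme that makes retinoic acid, had a log2 fold change of -3.07 and Calml3, a calmodulin-like protein of stratified epithelia, one of -2.94. Those of Rgs2, a regulator of G protein signalling, Psca and Ccdc3 were -2.70, -2.64 and -2.53, and the adjusted p of these 8 genes after Fosb lay between 0.022 and 0.040. A single library moved several of these values by over 1.5 times: without M3-CKO replicate 3 the log2 fold change was 3.83 for Scgb1a1 (5.23 with it), -5.38 for Car12 and -3.74 for Aldh1a3. It was 6.13 for Apobr without Ctrl replicate 3, -3.69 for Lgi2 without Ctrl replicate 1 and -2.35 for Calml3 without Ctrl replicate 2.

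**Figure D2:**
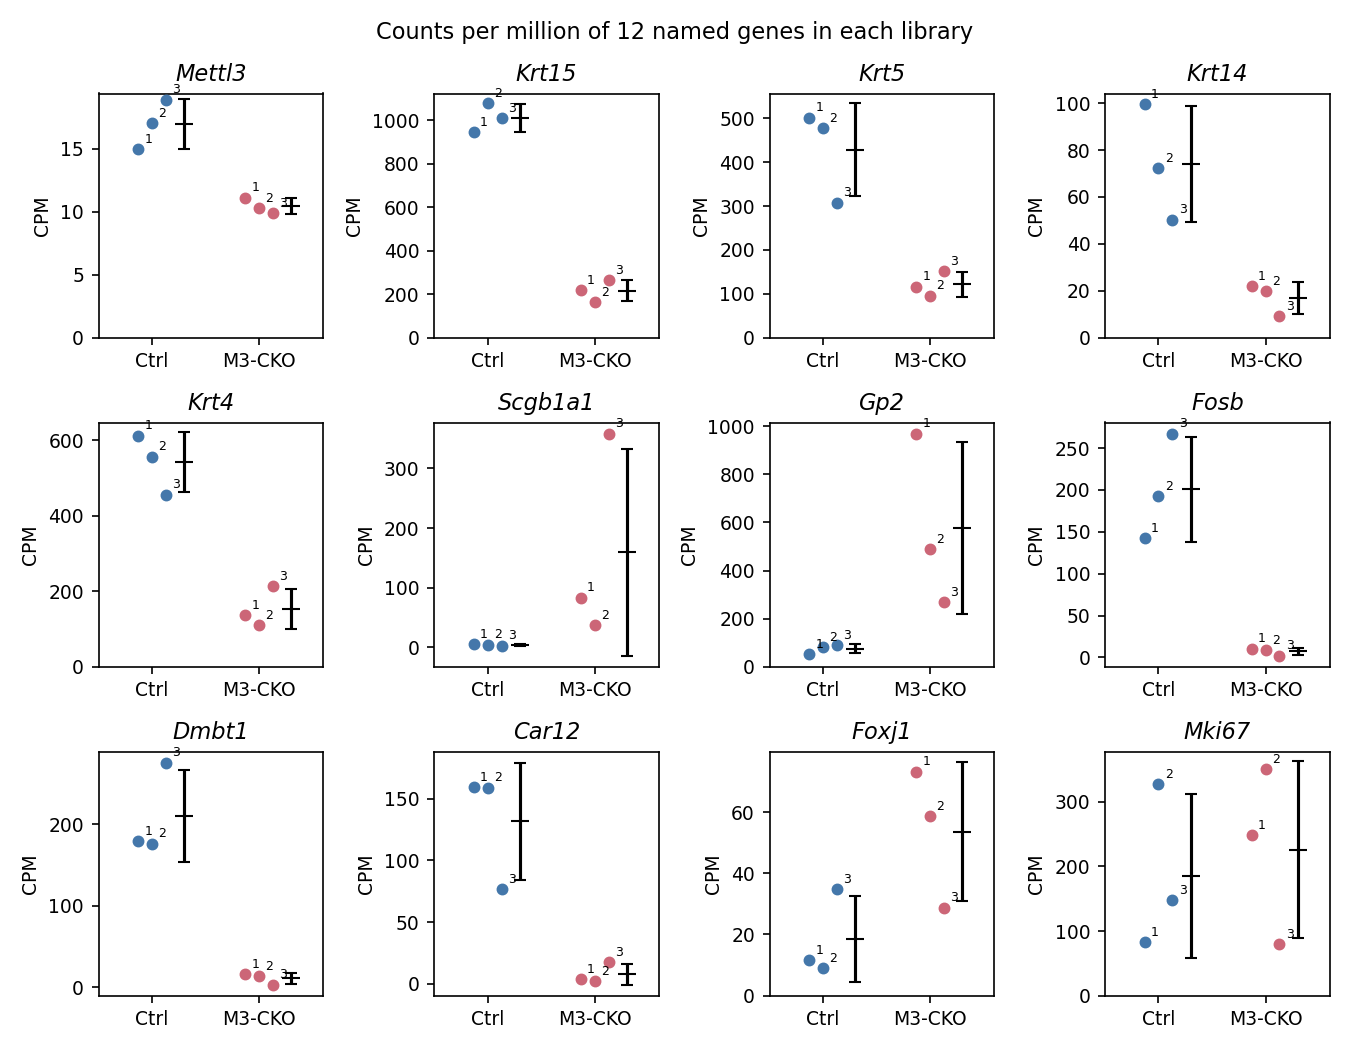
CPM (linear axes) of 12 named genes in each library, blue for Ctrl and red for M3-CKO, with the replicate number beside each point and the mean ± SD of 3 libraries as a black bar. Krt15 lies between 947 and 1078 CPM in Ctrl and between 165 and 264 in M3-CKO, while the groups overlap for Foxj1 and Mki67.

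The basal cell keratins Krt15, Krt5 and Krt14 were lower in M3-CKO organoids. Krt15 fell from 1012 ± 65.5 to 215.9 ± 49.4 CPM (log2 fold change -2.23, SE 0.21, adjusted p = 0.0083). Krt5 fell from 429 ± 105.7 to 121.6 ± 28.7 CPM (-1.82, SE 0.26, adjusted p = 0.024), and Krt14 from 74.1 ± 24.7 to 17.0 ± 6.95 CPM (-2.13, SE 0.38, adjusted p = 0.037). Of the 14 genes of the basal cell list 3 fell, 0 rose and 11 were not called, with a median log2 fold change of -0.75. Adjusted over the list alone, 7 fell and 1 rose, and DESeq2 called 6 lower and 1 higher. Trp63, the transcription factor that marks basal cells, had a log2 fold change of -0.81 (SE 0.28, adjusted p = 0.16), which was called without M3-CKO replicate 3 (-1.17, adjusted p = 0.0034). The list was called lower by camera (adjusted p = 6.7e-07). The call was lost with an estimated correlation (adjusted p = 0.38) and with fry (adjusted p = 0.080). Without M3-CKO replicate 3, whose levels of 9 of the 14 genes lay above the mean of replicates 1 and 2, 10 fell and 2 rose, with a median of -1.20.

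Genes of hillock and squamous cells, the flattened layered cells of airway epithelium, were the other list called lower. Krt4 fell from 541.2 ± 79.1 to 152.8 ± 53.8 CPM (log2 fold change -1.82, SE 0.27, adjusted p = 0.027), and the cornified envelope gene Sprr1a from 120.4 ± 17.1 to 62.4 ± 9.12 CPM (-0.95, SE 0.18, adjusted p = 0.039). The other 10 of 12 tested members were not called, and adjusted over the list alone 3 fell and 0 rose. Krt13, the usual hillock keratin, had a log2 fold change of -3.21 (SE 0.87, adjusted p = 0.092), which was -2.62 without Ctrl replicate 2. Its CPM was 2.40, 25.0 and 17.3 in Ctrl replicates 1 to 3, and 2.22, 2.05 and 0.509 in M3-CKO replicates 1 to 3. Ctrl replicate 1 thus lay close to M3-CKO replicates 1 and 2, and the difference rests on Ctrl replicates 2 and 3. Krt13 was called without M3-CKO replicate 3 (-2.79, adjusted p = 0.044), without a low-count filter (adjusted p = 0.024) and by DESeq2 (adjusted p = 4.1e-04). The median was -0.83 and the camera adjusted p was 0.0051. With an estimated correlation the adjusted p was 0.38, and with fry it was 0.029. The call was lost when replicate 3 of both groups was left out (adjusted p = 0.061). Of the 12 tested members, 2 had a positive log2 fold change. The larger was that of Sprr2a3 (1.94, SE 0.77, adjusted p = 0.21), which was 0.43 without M3-CKO replicate 3 (chosen after its values were seen). Loricrin is a squamous gene that the list holds under a newer name than the deposited symbol Lor. It was therefore not matched, and no list test was run with it. Against the direction of the list it rose from 0.258 ± 0.229 to 6.55 ± 2.11 CPM (log2 fold change 4.61, SE 0.73, adjusted p = 0.029). This gene was chosen after its values were seen.

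Club cell genes had no common direction between the groups. Scgb1a1 was the only 1 of 15 tested members that was called, also when adjusted over the list alone, with a log2 fold change of 5.23 (SE 0.89, adjusted p = 0.033). Its CPM was 83.2, 37.5 and 358.5 in M3-CKO replicates 1 to 3. The list's median was -0.41 and its mean 0.26, so the signs differ, and camera gave the direction down (adjusted p = 0.42). All 15 members were higher in M3-CKO replicate 3 than the mean of replicates 1 and 2, by a median of 2.00 on the log2 scale. Without replicate 3, 9 of the 15 fell and 1 rose, with a median of -1.10 and a camera adjusted p of 4.4e-06, and with an estimated correlation the adjusted p was 0.49. The summed CPM of the 16 listed genes was 12457 ± 117.5 in Ctrl, and 6022, 5309 and 16111 in M3-CKO replicates 1 to 3.

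Gp2, a membrane glycoprotein in the goblet cell list, rose from 74.1 ± 18.8 to 576.3 ± 358.3 CPM (log2 fold change 2.96, SE 0.47, adjusted p = 0.029; 2.36 without M3-CKO replicate 1). It was the only called member of 7 tested (2 rose adjusted over the list alone), and the list had a median of 0.53 and a camera adjusted p of 0.20. The gel-forming mucin Muc5ac had a log2 fold change of 0.01 (SE 0.59, adjusted p = 1.00), at about 3.16 CPM in both groups, and its sign changed with the libraries used. Foxj1, the regulator of motile cilia, stood at 18.5 ± 14.2 CPM in Ctrl and 53.5 ± 22.6 in M3-CKO (1.53, SE 0.55, adjusted p = 0.17; 0.026 without M3-CKO replicate 3 and 0.027 by DESeq2). Of 13 multiciliogenesis regulators and 11 motile cilia genes tested, 0 were called, 4 and 0 had an unadjusted p under 0.05, and DESeq2 called 1 and 0. Of these 4 regulators Foxj1 was higher, while Myb (-1.12), Ccno (-1.66) and E2f5 (-0.47) were lower (chosen after their values were seen). The regulators had a median of -0.47, with 4 of 13 positive (camera adjusted p = 0.41). The motile cilia genes had a median of 0.64, with 10 of 11 positive (camera adjusted p = 0.26). The motile cilia genes summed to 33.8 ± 18.6 CPM in Ctrl and 55.9 ± 20.6 in M3-CKO, so the depth behind each of them was low.

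**Figure D3:**
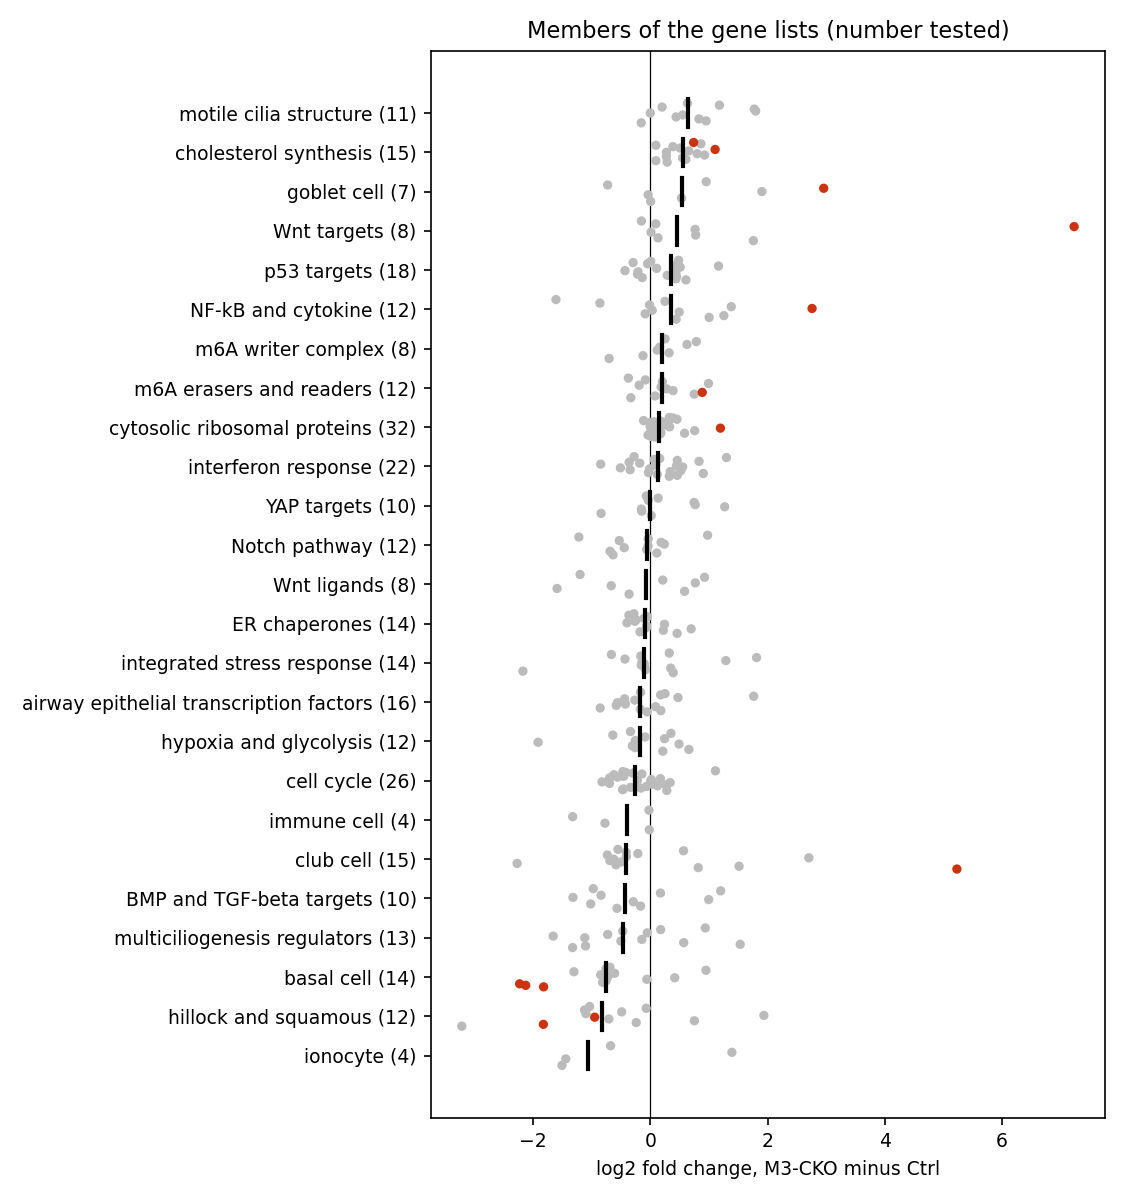
Log2 fold changes, M3-CKO minus Ctrl, of the tested members of 25 gene lists, 1 point per gene, red where the adjusted p is under 0.05 and grey otherwise, with the list's median as a black bar and the number of tested members in brackets. The medians of the called lists are -0.75 (basal cell), -0.83 (hillock and squamous), 0.55 (cholesterol synthesis) and 0.45 (Wnt targets). The point of Sp5, at the right, is a fitted value against a group with 0 counts and is no estimate of size.

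Of the enzymes of cholesterol synthesis, 2 of 15 tested were called, both higher in M3-CKO. Msmo1, a sterol C4 methyl oxidase, rose from 136.5 ± 22.8 to 294.0 ± 13.5 CPM (log2 fold change 1.11, SE 0.17, adjusted p = 0.028), and Sc5d, a sterol desaturase, from 138.9 ± 16.02 to 232.0 ± 16.9 CPM (0.74, SE 0.15, adjusted p = 0.049). All 15 members had a positive log2 fold change, 6 were called when adjusted over the list alone, and the median was 0.55. Camera called the list higher (adjusted p = 4.9e-05), and the call was lost with an estimated correlation (adjusted p = 0.70), with fry (adjusted p = 0.093) and when replicate 3 of both groups was left out (adjusted p = 0.068).

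The list of Wnt targets was called higher (camera adjusted p = 0.024, median 0.45), with 1 of 8 tested members called and 3 when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.70). The called member was Sp5, a transcription factor induced by Wnt signals. It had 0 counts in all Ctrl libraries and 2.70, 1.598 and 1.63 CPM in M3-CKO replicates 1 to 3, at least 18.4-fold higher than a floor of 3 counts over the Ctrl group (adjusted p = 0.035). Sp5 is the highest member, so setting it at that bound cannot move the list's median of 0.45, and the list's mean became 0.95 in place of 1.33. The adjusted p was 0.093 with fry, 0.13 without a low-count filter, and 0.066 and 0.064 without M3-CKO replicates 1 and 2. Among the 8 tested Wnt ligands 0 were called, 2 had an unadjusted p under 0.05, and DESeq2 called 1.

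Of the m6A erasers and readers, Ythdf2, a reader known for promoting decay of methylated mRNA, rose from 113.4 ± 6.98 to 209.6 ± 22.3 CPM (log2 fold change 0.89, SE 0.15, adjusted p = 0.032). The other 11 tested were not called, 3 rose when adjusted over the list alone, and the list's camera adjusted p was 0.37. In the writer complex 0 of 8 members were called, although 1 rose and 1 fell when adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 1. Tnf, an inflammatory cytokine, rose from 3.60 ± 0.579 to 24.5 ± 14.8 CPM (log2 fold change 2.76, SE 0.56, adjusted p = 0.048). It was the only called member of 12 in the list of NF-kB and cytokine genes (1 rose and 1 fell adjusted over the list alone), whose camera adjusted p was 0.57, or 0.014 without M3-CKO replicate 3. In that setting the adjusted p was 0.49 with an estimated correlation. Rpl37a, a ribosomal protein gene, rose from 7.59 ± 1.37 to 17.4 ± 0.508 CPM (log2 fold change 1.20, SE 0.23, adjusted p = 0.043). The remaining 31 of 32 cytosolic ribosomal protein genes were not called, the list's median was 0.14 and its camera adjusted p 0.13. Ribosomal protein genes have many processed copies in the genome, so the Rpl37a count is uncertain.

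Of the 25 tested lists, 16 had no called member, with 0 to 4 members each at an unadjusted p under 0.05 and 0 to 2 called by DESeq2. Besides those given above, they were cell cycle (median -0.26), p53 targets (0.35), interferon response (0.14), the Notch pathway (-0.05), BMP and TGF-beta targets (-0.43), the integrated stress response (-0.10), ER chaperones (-0.08), hypoxia and glycolysis (-0.17), airway epithelial transcription factors (-0.17), YAP targets (-0.01), ionocytes (-1.06) and immune cells (-0.40). Camera gave these 12 lists adjusted p from 0.41 to 0.76. For YAP targets and the integrated stress response the mean was positive (0.17 and 0.01), as was camera's direction, against a negative median. The YAP targets reached an adjusted p of 0.036 in the upward direction without M3-CKO replicate 3, and 0.57 with an estimated correlation. The proliferation marker Mki67 had a log2 fold change of 0.28 (SE 0.61, adjusted p = 0.84), the cell cycle inhibitor Cdkn1a 0.61 (SE 0.52, adjusted p = 0.56; 0.049 without M3-CKO replicate 3) and the interferon-induced Isg15 0.90 (SE 0.69, adjusted p = 0.52).

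Those markers of cells that a tracheal preparation can carry along which had a row were low, apart from the immune list. Rows were held for 7 of 13 mesenchymal, 6 of 10 endothelial, 5 of 8 cartilage, 7 of 14 immune and 2 of 6 erythrocyte genes. The erythrocyte genes with a row include no haemoglobin gene. The other listed genes have no value here, so the sums do not cover them. The mesenchymal genes with a row summed to 9.20 ± 4.51 CPM in Ctrl and 3.42 ± 0.841 in M3-CKO. The endothelial genes reached 2.16 ± 0.805 and 3.43 ± 0.436, and the erythrocyte genes 0.508 ± 0.347 and 0.655 ± 0.134. The cartilage genes reached 2.03 ± 0.826 and 1.51 ± 0.544. Of this, Chad, which is also in the club cell list, made up 1.52 and 1.31 (chosen after its values were seen). The immune genes summed to 960.4 ± 447.6 and 592.6 ± 180.1 CPM, of which Lyz2, a lysozyme gene that airway epithelium can also express, made up 876.3 and 512.7 (chosen after its values were seen). The rarer epithelial types reached sums of 147.4 ± 38.9 and 146.0 ± 14.1 CPM for tuft cells, of which Dclk1 made up 143.3 and 140.2, and 5.56 ± 2.19 and 8.37 ± 4.13 for neuroendocrine cells. The list of EMT regulators summed to 290.1 ± 25.6 and 355.9 ± 106.3 CPM, of which Fn1, which encodes the matrix protein fibronectin, made up 263.3 and 339.0. Dclk1 and Fn1 were chosen after their values were seen. These lists, except the immune one, and the mitochondrially encoded genes had fewer than 4 tested members, so no list test was run for these 8, and 0 of their tested genes were called, with 1 at an unadjusted p under 0.05 and 1 called by DESeq2 (Pdgfra, lower in M3-CKO; chosen after its values were seen).

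**Figure D4:**
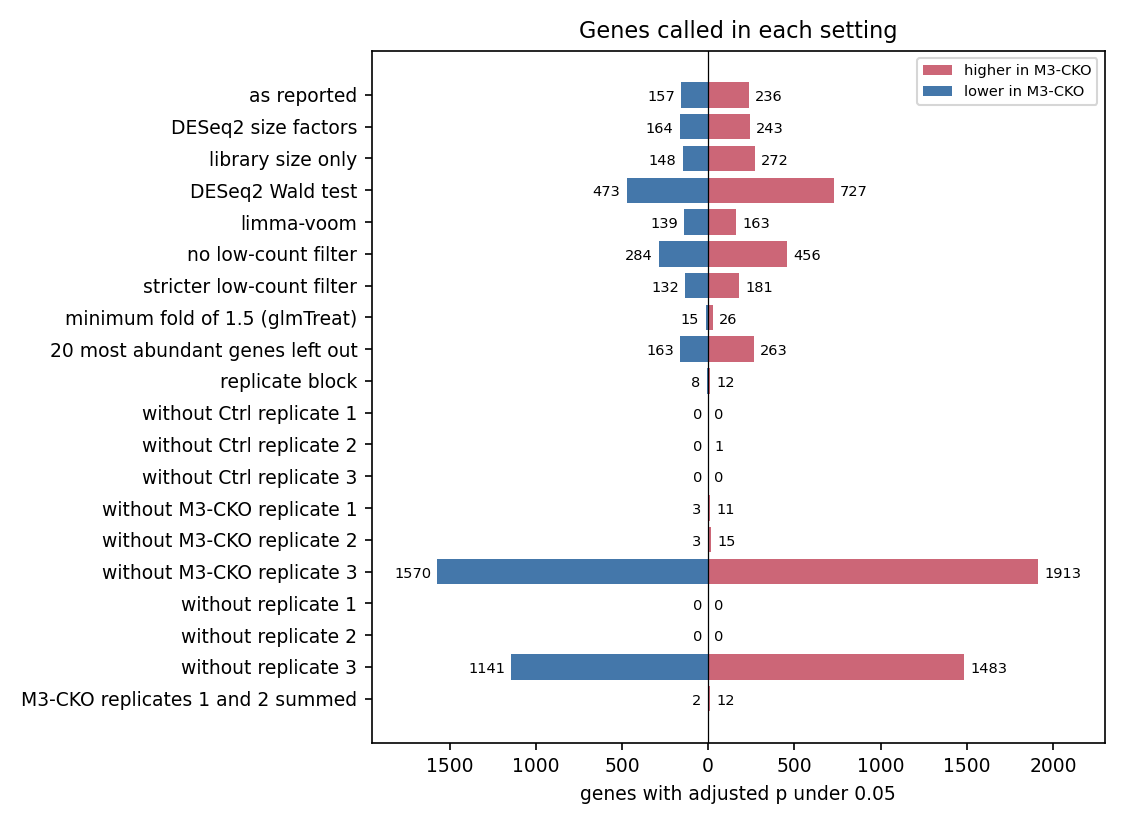
Number of genes with an adjusted p under 0.05 in each setting, higher in M3-CKO to the right in red and lower to the left in blue, with each number at the bar. The count of 236 higher and 157 lower as reported becomes 1913 and 1570 without M3-CKO replicate 3.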

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

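Every alternative here was set before the data were examined, except the summing of M3-CKO replicates 1 and 2. The 393 called genes became 407 with DESeq2 size factors, 420 with library size alone, 302 with limma-voom, 313 with a stricter filter and 426 without the 20 most abundant genes. Larger moves came with the DESeq2 Wald test (1200, including all 393), with no low-count filter (740, including 385), with a minimum fold of 1.5 (41, 26 higher and 15 lower), with the replicate number as a block (20, 12 higher and 8 lower) and with M3-CKO replicates 1 and 2 summed (14). With libraries left out, singly or as 1 replicate number of both groups, the count ran from 0 to 3483. It was 0 in edgeR without replicate 1 or 2 of both groups (1309 and 1335 at an unadjusted p under 0.05) and 2624 without replicate 3 of both. The labels do not say whether a number marks a shared day, so the plan made before the data were examined did not treat libraries as pairs. Same-numbered libraries did not deviate together (correlations -0.026, 0.015 and -0.103, and 0 of 3 matched its own number best). This check cannot settle the question, because M3-CKO replicate 3 dominates the deviations from the mean of its group. The block fit changed no list call. The edgeR biological coefficient of variation was 0.291 with all libraries and 0.177 without M3-CKO replicate 3. The cause of the moves with the test, the filter and the minimum fold was not tested.

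The Mettl3 log2 fold change ranged from -0.78 to -0.62 without single libraries, and from -0.83 to -0.59 when leaving out 1 replicate number of both groups is included. It passed the threshold without M3-CKO replicate 3 (-0.67, adjusted p = 0.043) and in no other setting run (adjusted p up to 0.91). Of the 4 lists called with the preset correlation, 0 were called with an estimated correlation (2 lists had an unadjusted p under 0.05) and 1 with fry. The count ran from 3 to 7 with libraries left out in either way. Medians are the same by construction in both tests: -0.75 (basal cell), -0.83 (hillock and squamous), 0.45 (Wnt targets) and 0.55 (cholesterol synthesis). With libraries left out in either way the hillock and squamous median ranged from -0.92 to -0.59, Wnt targets from 0.39 to 0.88, cholesterol synthesis from 0.42 to 0.67 and basal cell from -1.39 to -0.50. Wnt targets also lost their call without a filter (median 0.36, adjusted p = 0.13, more genes tested) and with the summed replicates (0.37, adjusted p = 0.054). The direction of these 4 lists did not change in any setting.

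For the genes that the naming rule picked, other than Mettl3, 739 pairs of gene and setting gave 409 with the same direction and side of the threshold, 312 with a lost call, 9 with a gained call and 9 with the other sign. The sign changed for Muc5ac (-0.70 to 0.99 with libraries left out in either way, -0.044 with the summed replicates) and Mki67 (-0.17 to 0.97), and both have adjusted p above 0.2 in every such setting. Of the 32 called genes among them, 32 stayed called with DESeq2 and with no filter, 19 with limma-voom, 9 with the minimum fold and 5 with the block, and 0 reversed in any setting. Depth limits genes of few counts, such as the cilia genes. The comparisons planned for the m6A immunoprecipitation libraries, and their alternatives, were not run.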

Other observations

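The gene lists in this part, the weighing of chance, and the tests on gene families, control-like cells, long transcripts and depth were chosen after the results were seen. Only the tests of the segment around Mettl3 and of a doubled library were set before their outcome was seen, the second after the close correlation of that pair was known.

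Some immediate early transcription factors were lower in M3-CKO organoids. Besides Fosb, Ier2 fell by 1.16 on the log2 scale (SE 0.17, adjusted p = 0.027), and Fos, Egr1 and Atf3 had log2 fold changes of -2.49, -1.78 and -2.17 that were not called (adjusted p = 0.082, 0.16 and 0.18). Of 13 such genes tested, 2 fell and 0 rose, with a median of -1.15. Without M3-CKO replicate 3, 4 fell and 2 rose. These genes are known to respond within minutes to handling and to growth factors.

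In the Regenerating family, which encodes secreted lectins, 3 of 5 tested genes rose. Reg1 rose from 42.1 ± 12.4 to 397.7 ± 55.8 CPM (log2 fold change 3.24, SE 0.25, adjusted p = 0.0068), Reg3d from 2.68 ± 0.771 to 24.5 ± 0.996 CPM (3.19, SE 0.28, adjusted p = 0.0068) and Reg3a by 2.81 on the log2 scale (adjusted p = 0.047). Reg3g, the most abundant member, stood at 3370 ± 149.9 CPM in Ctrl and 2533 ± 1239 in M3-CKO (-0.41, SE 0.32, adjusted p = 0.53). Without M3-CKO replicate 3 the family had 4 genes that rose and 1 that fell, Reg3g (-0.89, adjusted p = 0.0031). The members are similar in sequence and lie side by side, so shared reads are an open limit.

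M3-CKO replicates 1 and 2 lay close together and replicate 3 lay apart. The close pair differed by more than sampling noise (chi-square over degrees of freedom 6.14), which argues against 1 library counted again as another, and the total of replicate 3, 9424349 counts, lay within the range of the others, which argues against shallower sequencing. Control-like cells that kept Mettl3 would, as the only difference, place replicate 3 between the groups. Yet 243 of 7783 abundant genes lay over 2-fold outside the range of the other 5 libraries, against at most 23 for any other library. This argues against such cells as the only difference, but cannot exclude them beside another difference. Mettl3 was lowest in replicate 3 (9.87 CPM, with 11.1 and 10.3 in replicates 1 and 2, and at least 14.96 in Ctrl). Its whole-gene count does not measure intact transcript, however. Apobr did lie between in replicate 3 (16.4 CPM, with 106.0 and 73.7 in replicates 1 and 2, and at most 4.27 in Ctrl). Scgb1a1 did not (358.5 CPM, with 83.2 and 37.5 in replicates 1 and 2). Loss of long transcripts stays open because its measures part: their median difference from replicates 1 and 2 was -0.24 (95% bootstrap interval -0.50 to 0.15, with 10 of 25 lists below it), but they summed to 3478 CPM in replicate 3 against 5821 to 7017 in the other 5 libraries, a gap that narrows without Ahnak (2771 against 3442 to 4382), and 61.5% of them were lower against 49.3% of all tested genes and 37.5% of ribosomal protein genes. These measures were set, and the reading of them changed, after the values were seen. The long transcripts were picked by name and no lengths were measured, and the bootstrap treated the genes as independent. Some are also in cell type lists, such as Dst (basal cell) and Muc5b (club cell), both chosen after their values were seen. A part played by culture or genotype also stays open. Beyond control-like cells no biological explanation was tested, because the labels name no group that holds replicate 3 alone.

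Relative to the mean of M3-CKO replicates 1 and 2, replicate 3 was lower in all 22 interferon response genes (median -1.41), in 24 of 26 cell cycle genes (median -0.88) and in all 10 YAP targets (median -0.89), and higher in all 15 club cell genes. The low interferon response level was not particular to this library: the listed genes summed to 839 CPM in it and to 699 CPM in Ctrl replicate 3, against 1421 to 2424 CPM in the other 4 libraries.

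The 393 called genes were set against chance and against the genome around the target. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05: 1 of the 10, the real one, gave 393 genes in edgeR, and the highest of the other splits gave 0 (1481 at an unadjusted p under 0.05, against 2774). A genome segment carried along with the Mettl3 allele may change its neighbours. Among the 100 tested genes nearest to Mettl3 there were 2 called genes where 2.87 were expected (one-sided exact hypergeometric p = 0.79). This argues against such a segment as the source of most of the calls. The test cannot exclude small changes of a few neighbours, because the simulated changes of 2-fold were often missed.

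Called genes lay side by side in the genome in 19 pairs, where shuffled calls gave 11.0 on average (permutation p = 0.015). A candidate explanation is gene families whose members are changed or counted together, such as Ugt1a6a and Ugt1a6b (which share exons), Naip5 and Naip6, or Reg3a and Reg3d, all chosen after their values were seen. Without the 6 pairs whose names share their first 3 letters, 13 pairs remained where shuffling gave 10.53 (permutation p = 0.26). This is in line with families as the source of the excess, although the test does not exclude a smaller excess among unrelated neighbours. The names miss some families, such as Ltb and Tnf, 2 cytokines of the TNF family whose pair was left in.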
